A study of Mus musculus with 6 samples.

How the data were processed

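Total RNA of 6 samples of mouse dermal fibroblasts at passage 4 was measured on Affymetrix mouse 430 2.0 arrays, 2 each of untreated control cells, treated GFP-negative cells and treated GFP-positive cells. Dose and times (4 μM, 48 hours and 24 hours of recovery) and groups were taken per the labels. The deposited values were 1 signal intensity per probe set and array on a linear scale, made by MAS5 per the submitters' processing notes; its version and settings are not given in the sources used here. The deposited table held 45101 probe sets. The 2% trimmed mean of the deposited intensity was 500.003 or 500.004 on 4 arrays, but 62.0 on GFP-negative replicate 2 and 50.5 on GFP-positive replicate 2. By a rule fixed beforehand for trimmed means that differ by over 10%, each array was scaled to a trimmed mean of 500.003, with factors of 8.06 and 9.90 for these arrays and of 1 to the digits given for the others.

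After leaving out 64 control probe sets, 45037 remained, of which 34945 had 1 gene symbol, 932 had several and 9160 were unnamed here. Chromosomes came from a table of mouse genes, to which 34741 were matched; positions within a chromosome were not used here. An offset of 30.64, the median over arrays of the 25th percentile, was added before taking log2. Probe sets were kept if their mean signal over the 6 arrays reached the 40th percentile of such means (67.71), which left 27022 probe sets and 13223 genes, of which 443 are X-linked. Gene lists used the brightest probe set of each gene.

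Comparisons were made in R 4.3.3 with limma 3.58.1: linear models over all 6 arrays, eBayes with a mean-variance trend, two-sided moderated tests with 3 residual degrees of freedom and Benjamini-Hochberg adjustment over all probe sets, with an adjusted p under 0.05 called. The contrasts were GFP-positive against control, GFP-negative against control, GFP-positive against GFP-negative, and the mean of both treated groups against control. Treated cells differ from control cells also by the further sort, and this cannot be told apart from the drug. The labels do not say whether the replicates came from separate cultures or animals beyond calling them biological, so p-values measure the spread between these samples.

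Gene lists were tested with camera of limma at an inter-gene correlation of 0.01, adjusted over 20 lists per comparison. They were tested again with a correlation estimated from the residuals, with which 0 of the 16 list calls over the 3 comparisons remained. That setting also lowers the degrees of freedom of the test to the residual ones (3 without a block). A call lost with it is thus not lost through correlation alone. For the p53 targets in GFP-positive against control cells the estimated correlation was 0.0076, yet the camera p went from 3.51e-05 to 0.0235. The lists were imprinted, germline, interferon response, p53 target, cell cycle, DNA methylation machinery, extracellular matrix and fibroblast identity, stress and metallothionein, inflammatory secreted, X-inactivation escape, Y-linked and X chromosome genes, and markers of keratinocytes, melanocytes, endothelial cells, leukocytes, skeletal muscle, smooth muscle, adipocytes and Schwann cells. Counts over a list are also given adjusted over the list alone. X-linked and autosomal calls were compared with Fisher's exact test.

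The groups, contrasts, lists, offset, filter and alternatives were chosen before the data were examined. The genes to be named were, for each comparison, the 12 largest called rises and falls with 1 symbol and no overlap of groups, clone-type symbols left out, each at its called probe set of smallest p, up to 4 members of smallest p of each list, and Xist, Dnmt1, Cdkn1a, H19 and Y-linked genes. Members of lists that were not called are not named, of the Y-linked genes 4 are, and H19 was not analysed here, since no probe set carried it as a single symbol. The alternatives were quantile normalization, median centring, other offsets and filters, no trend, the replicate number as a block, only the groups compared, probe sets of the types that bind related transcripts left out, the mean of the probe sets of a gene, other thresholds, and leaving out each array. Chosen after seeing the data were the block with quantile normalization, the block without a trend, the block with an estimated correlation, leaving out both rescaled arrays, and 5 gene families in the closing part.

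The fits were tested on simulated data for GFP-positive against control, with 27022 probe sets of which 200 were changed. With the difference between the array sets built in, limma as used here recovered 0% of changes of 2-fold, 11.9% of 4-fold and 57.6% of 16-fold with 0 false calls, and the block recovered 49.3%, 79.1% and 93.9% with 17 false calls beside 148 true ones. Without that difference limma as used here made 11 false calls beside 146 true ones and the block 18 beside 146. Without a trend 0%, 0% and 47.0% were recovered, and with the block and no trend 0%, 19.4% and 92.4%, each with 0 false calls. The noise in these simulations came from the blocked fit, and the difference between the array sets was the same in all groups, as the block assumes. Of 20 simulated lists, all 5 shifted by 0.5 and 0 of the others were called. Genes of these lists were simulated independently and without a difference between array sets, so false calls from correlated genes could not appear. The germline list had an estimated correlation of 0.37.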

Results

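The data were 6 Affymetrix arrays of the mouse 430 2.0 design, hybridised with total RNA from cultured dermal fibroblasts of newborn mice. The mice carried a GFP transgene on the X chromosome, and cells that did not express it were collected by cell sorting. Per the labels the transgene came from the father and lay on the inactive X in these cells. Control replicate 2 is labelled as of mixed sex, and male cells would lack the transgene. There were 3 groups of 2 arrays, which the labels call biological replicates. Control cells were left untreated and were not sorted again. The other cells received 5-aza-2'-deoxycytidine, an inhibitor of DNA methylation, at 4 μM for 48 hours, and recovered for 24 hours. They were then sorted a further time into GFP-positive cells, in which the transgene had become active, and GFP-negative cells. The table held 1 signal for each of 45101 probe sets and array, and 27022 probe sets, covering 13223 named genes, were bright enough to be tested. The number of arrays limits the precision of every value. Fold changes are given as log2 differences with their standard error (SE) on the scale of signal plus an offset of 30.64, which understates the change of dim probe sets. Signals are means ± SD of 2 arrays.

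The arrays numbered 1 and those numbered 2 differed in every group. After scaling, the lower quartile of the signal was 38.7 to 42.6 on the replicate 1 arrays and 19.2 to 22.6 on the replicate 2 arrays, and the median was 122.6 to 134.8 against 79.8 to 81.1. Each array set held 1 array of each group, so changes within a set are printed for the gene lists and for some genes. Every gene named in this part as called in either treated group against control changed in the same direction within both sets. Values with the array set as a block are printed beside the counts and the called lists. Fits that leave out 1 array have no block and make the array sets uneven between groups. Their values therefore also hold the difference between the sets. In simulated data the block made 17 false calls beside 148 true ones with the difference between the array sets and 18 beside 146 without it, where the fit without a block made 0 beside 46 and 11 beside 146.

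The comparison of GFP-positive with control cells asked which genes differed in cells that had reactivated the transgene. Large rises among the genes named here were those of Asb5, an adaptor of a ubiquitin ligase, by 5.08 ± 0.38 (SE; 4.62 within replicate 1 and 5.54 within replicate 2; adjusted p = 0.0125), and of Krt8 by 4.89 ± 0.29 (4.64 and 5.14; adjusted p = 0.00603). A probe set without a gene name was at 7.33 and the clone-type Gm9222 at 6.34, both of a type that can bind related transcripts. The signal of Krt8, a keratin of simple epithelia, went from 16.3 ± 4.5 in control to 1365 ± 207.2 in GFP-positive cells. On its other probe sets Krt8 rose less, by 3.55 and 4.22. Its partner keratin Krt18 rose by 3.89 ± 0.30 (3.66 and 4.11; adjusted p = 0.0125), from 229.7 ± 26.8 to 3905 ± 1244. Genes of the germline list rose as well. Dazl, an RNA-binding protein of the germ line, rose by 4.37 ± 0.45 on its probe set of smallest p (4.54 and 4.19; adjusted p = 0.0286) and by 5.58 on its other one, which was called too. Gtsf1, a factor of the piRNA pathway, rose by 3.83 ± 0.45 (3.38 and 4.29; adjusted p = 0.0399), or by 2.53 with 4 times the offset. The homeobox gene Rhox5 rose by 3.63 ± 0.42 (3.96 and 3.30) and Tex19.1 by 3.25 ± 0.41 (3.58 and 2.93), with adjusted p-values of 0.0376 and 0.0456. The largest fall was that of Ccn3, a secreted matricellular protein, by -4.95 ± 0.44 (-4.74 and -5.16; adjusted p = 0.0163), from 12606 ± 4002 to 395.2 ± 214.6.

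In all, 33 of the 27022 probe sets passed an adjusted p of 0.05, of which 24 were higher and 9 lower in GFP-positive cells, and they covered 22 named genes. U90926 rose by 3.76 ± 0.44, Noct (nocturnin) by 2.81 ± 0.25, the cardiac ankyrin repeat protein Ankrd1 by 2.61 ± 0.29, Phlda1 by 2.28 ± 0.22 and Tpd52l1 by 2.22 ± 0.27, with adjusted p-values between 0.0163 and 0.0456. The other falls with a gene name were Epha3, a receptor tyrosine kinase (-2.57 ± 0.30), the metalloproteinase Adamts1 (-2.14 ± 0.22), the protein kinase C substrate Marcks (-2.07 ± 0.23), the elastic fibre component Fbln5 (-1.96 ± 0.21), the RNA-binding protein Rbms3 (-1.91 ± 0.24) and Pappa, a protease of insulin-like growth factor binding proteins (-1.89 ± 0.24). The probe sets printed for Krt8, Gtsf1 and Ccn3 are of a type that can bind transcripts of related genes. All 3 Krt8 and both Ccn3 probe sets were called, and 1 of the 2 Gtsf1, 1 of the 2 Ankrd1 and 1 of the 7 Marcks probe sets. Such counts are not printed here for the other genes that fell. Limma without a mean-variance trend called 0 probe sets (1674 at an unadjusted p under 0.05). With the trend, 0 were called without GFP-positive replicate 2, 2 without control replicate 1, 8 without GFP-positive replicate 1 and 13 without control replicate 2. With the array set as a block the count was 1679, of which 852 were higher and 827 lower, and it included all 33, but without the trend the blocked fit called 8.

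**Figure D1:**
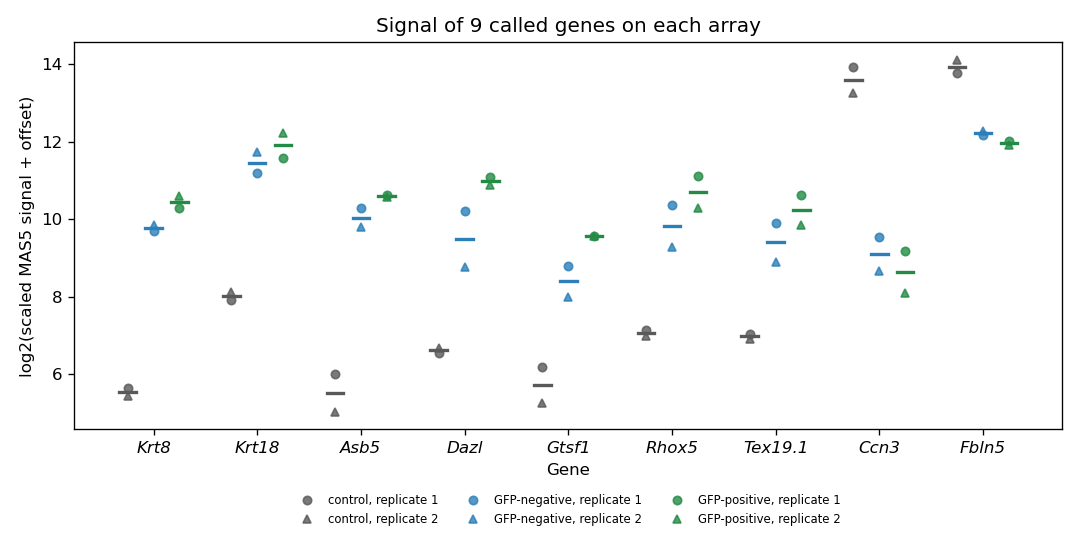
Value of log2(scaled signal + offset) for 9 genes called between GFP-positive and control cells, on each array; colours are groups, circles are replicate 1, triangles are replicate 2, and short bars are group means. For Krt8, Krt18, Asb5, Dazl, Gtsf1, Rhox5 and Tex19.1 all 4 treated arrays lay above both controls, and for Ccn3 and Fbln5 below both.

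Among the gene lists fixed before the data were examined, 7 of 20 differed from all other genes between GFP-positive and control cells. The germline list stood higher, with a median 0.67 above that of other genes (0.59 within replicate 1 and 0.81 within replicate 2; camera adjusted p = 3.64e-07, or 0.603 with an estimated correlation). Of its 35 measured members 29 were positive, 4 were called over all probe sets, namely Dazl, Gtsf1, Rhox5 and Tex19.1, and 7 were higher when adjusted over the list alone. With the block 8 members were higher. The shift was 2.38 with the stricter filter on dim probe sets, 0.43 without a filter and 0.40 with 4 times the offset. The list of extracellular matrix and fibroblast identity genes stood lower, with a median of -0.51 relative to other genes (-0.39 and -0.54; adjusted p = 4.10e-12, or 0.506 with an estimated correlation). Of its 46 members 38 were negative; 1, Fbln5, was called, and 12 were lower when adjusted over the list alone. Beside Fbln5 its members of smallest p were the mesenchymal homeobox gene Prrx1 (-1.01 ± 0.19), the thrombospondin Thbs2 (-1.01 ± 0.22) and Fap, a surface protease of activated fibroblasts (-2.02 ± 0.47), with adjusted p-values of 0.158, 0.223 and 0.271; Fap was at -1.33 without GFP-positive replicate 2. With the block 21 members were lower and 1 higher, and these 3 genes passed the test (adjusted p = 0.000808, 0.000685 and 0.00109).

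The cell cycle list stood 0.33 higher (0.24 and 0.45; adjusted p = 6.24e-07, or 0.543 with an estimated correlation), with 42 of 49 members positive and 0 called, or 5 higher with the block. Its members of smallest p were Rrm2, a subunit of ribonucleotide reductase (0.96 ± 0.23), the replication licensing factor Cdt1 (0.81 ± 0.25), the cyclin Ccne2 (0.95 ± 0.32) and the mitotic kinase Aurka (0.63 ± 0.23). The p53 target list stood 0.42 higher (0.25 and 0.33; adjusted p = 0.000175, or 0.469 with an estimated correlation); 25 of 37 members were positive, 0 were called, or 9 higher with the block, and 1 was higher when adjusted over the list alone. The values of Mdm2, the ubiquitin ligase of p53, were 2083 ± 407.4 in control and 6535 ± 1402 in GFP-positive cells (1.63 ± 0.25, adjusted p = 0.0813, or 4.83e-05 with the block), and the differences of Cd80, the cell cycle inhibitor Cdkn1a and Perp were 1.96 ± 0.49, 0.65 ± 0.20 and 1.53 ± 0.49; Cd80 was at 1.30 without control replicate 1 and Perp at 0.87 with 4 times the offset. The imprinted list stood lower by -0.17 (-0.28 and -0.22; adjusted p = 0.0139, or 0.679 with an estimated correlation) with 16 of 26 members negative, 0 called, or 4 lower and 1 higher with the block, and 2 lower when adjusted over the list alone. Peg3 was at -1.72 ± 0.24 (adjusted p = 0.0702, or 0.000165 with the block), Igf2r at -1.09 ± 0.22, Grb10 at -0.80 ± 0.22 and Slc38a4 at 1.04 ± 0.34, or 0.64 without GFP-positive replicate 2. That list lost its call without GFP-positive replicate 2, with a median of 0.02 and an adjusted p of 0.256, and without control replicate 1 (-0.07, 0.429), and it stood at -0.51 without control replicate 2, -0.56 without GFP-positive replicate 1 and -0.34 with the stricter filter. The cell cycle shift was 0.21 without GFP-positive replicate 2.

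The interferon response list stood 0.42 higher in GFP-positive than in control cells over all arrays (adjusted p = 0.00851, or 0.745 with an estimated correlation), with 33 of 39 members positive and 0 called, or 4 higher with the block. The shift was 0.86 within replicate 1 and -0.09 within replicate 2, so it did not hold within the second array set. Without GFP-positive replicate 1 it was 0.0096 (adjusted p = 0.974) and without control replicate 1 0.35 (0.0869), while without GFP-positive replicate 2 it was 0.82 and with 4 times the offset 0.26. The deubiquitinating enzyme of the interferon response Usp18 was 2.63 higher within replicate 1 and 0.89 within replicate 2, the chemokine Cxcl10 2.64 and 0.65, the RNA sensor Ifih1 1.66 and 0.37, and H2-D1, a class I histocompatibility gene, 1.15 and 0.93.

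**Figure D2:**
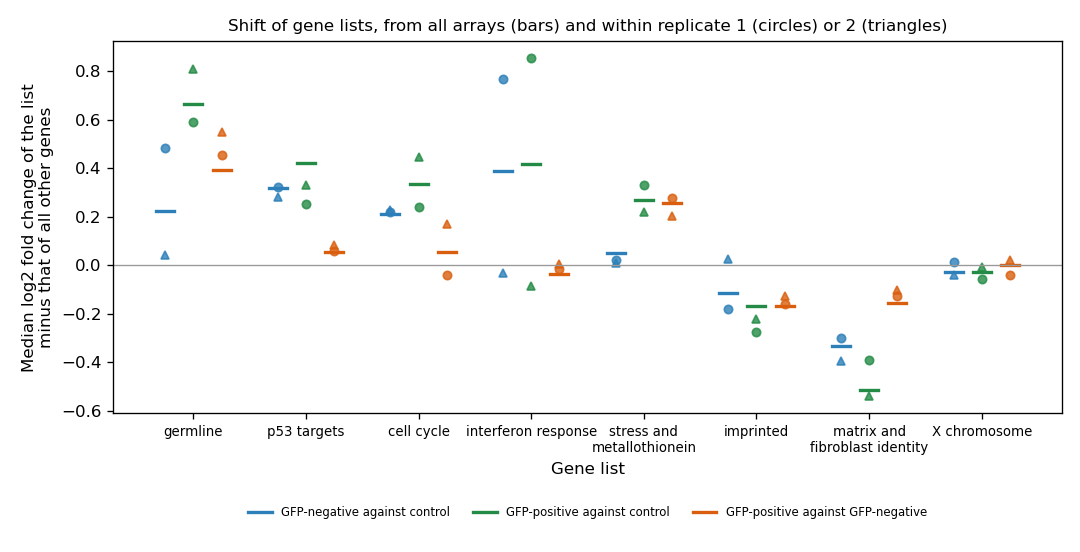
Median log2 fold change of each gene list minus that of all other genes, for GFP-negative against control (blue), GFP-positive against control (green) and GFP-positive against GFP-negative (orange); bars use all arrays, circles replicate 1 alone and triangles replicate 2 alone. The germline list lay above 0 in all 3 comparisons in both array sets, the matrix and fibroblast identity list below 0, and the interferon response list was at 0.86 and -0.09 in the GFP-positive cells of the array sets.

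The comparison of GFP-negative with control cells asked which genes differed in treated cells whose transgene had stayed silent. The genes that passed the test here were Asb5 (4.52 ± 0.38, adjusted p = 0.0351), Krt8 (4.22 ± 0.29, 0.0184), Krt18 (3.43 ± 0.30, 0.0351), Noct (2.39 ± 0.25, 0.0466) and Phlda1 (2.28 ± 0.22, 0.0386), which rose, and Ccn3, which fell (-4.49 ± 0.44, 0.0392). With 4 times the offset the difference of Krt8 was 2.80. At the offset of 30.64 its other probe sets were at 2.83 and 3.34. Krt18 reached a signal of 2816 ± 741.7 against 229.7 ± 26.8 in control, and Ccn3 went from 12606 ± 4002 to 542.4 ± 235.8. In all 8 probe sets were called, 7 higher and 1 lower, over 6 named genes. Limma without a trend called 0 (1298 at an unadjusted p under 0.05). With the trend the count was 0 without GFP-negative replicate 1, 1 without GFP-negative replicate 2, 2 without control replicate 1, 3 without GFP-positive replicate 2 and 5 without GFP-positive replicate 1. With the array set as a block 966 probe sets were called, 513 higher and 453 lower, with all 8 among them, and 0 without the trend. Centring each array on its median gave 4 calls, 2 in each direction.

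In GFP-negative against control cells 6 of the 20 lists were called. The matrix and fibroblast identity list was lower by -0.33 (-0.30 within replicate 1 and -0.40 within replicate 2; adjusted p = 9.70e-10, or 0.630 with an estimated correlation), with 37 of 46 members negative, 0 called, or 15 lower and 1 higher with the block, and 4 lower when adjusted over the list alone. Its members of smallest p were Fbln5 (-1.71 ± 0.21, adjusted p = 0.0827), Thbs2 (-1.02 ± 0.22) and the small leucine-rich proteoglycans Lum (-3.25 ± 0.73) and Ogn (-1.39 ± 0.33). The cell cycle list was higher by 0.21 (0.22 and 0.23; adjusted p = 5.82e-06, or 0.630 with an estimated correlation), with 45 of 49 members positive and 0 called, or 4 higher with the block. Rrm2 was at 1.02 ± 0.23, Ccne1 at 0.90 ± 0.27, the replication factor Cdc6 at 1.27 ± 0.39 and Ccne2 at 1.01 ± 0.32, the last 2 at 0.81 and 0.64 without GFP-negative replicate 2. The p53 target list was higher by 0.32 (0.32 and 0.28; adjusted p = 0.000104, or 0.418 with an estimated correlation), with 32 of 37 members positive, 0 called, or 5 higher and 1 lower with the block, and 2 higher when adjusted over the list alone. Mdm2 was at 1.14 ± 0.25, Cd80 at 2.17 ± 0.49, Cdkn1a at 0.61 ± 0.20 and Ckap2 at 0.93 ± 0.34, or 0.58 without GFP-negative replicate 1.

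The germline list was 0.22 higher in GFP-negative than in control cells (0.48 within replicate 1 and 0.04 within replicate 2; adjusted p = 0.000402, or 0.682 with an estimated correlation), with 26 of 35 members positive, 0 called, or 5 higher with the block, and 4 higher when adjusted over the list alone. Without GFP-negative replicate 1 its median was -0.14 (adjusted p = 0.107), without GFP-negative replicate 2 it was 0.72, and without control replicate 1 or 2 it was 0.35 or 0.06. With the stricter filter it was 1.26. Dazl was at 2.87 ± 0.45, Rhox5 at 2.76 ± 0.42, Gtsf1 at 2.67 ± 0.45 and Tex19.1 at 2.42 ± 0.41, and each was above control within both array sets. With 4 times the offset Gtsf1 was at 1.56. The interferon response list was 0.39 higher (adjusted p = 0.00280, or 0.720 with an estimated correlation), with 32 of 39 members positive and 0 called, or 2 higher with the block. It was at 0.77 within replicate 1 and -0.03 within replicate 2, so it did not hold within the second array set. Without GFP-negative replicate 1 the shift was 0.07 (adjusted p = 0.938), without control replicate 1 it was 0.27 (0.0532), and without GFP-negative replicate 2 it was 0.86. Usp18 was 2.75 and 0.92 higher within the array sets, Cxcl10 2.69 and 0.44, the antiviral gene Ifit1 2.24 and 0.20, and the transcription factor Irf7 0.98 and 0.82.

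Both treated comparisons used the same control arrays. All 8 probe sets called in GFP-negative cells were also called, in the same direction, in GFP-positive cells. Independent lists of these sizes would share 0.00655 probe sets in the same direction, and 100 simulations of unchanged groups against shared controls gave a mean overlap of 0.02 and a highest of 1. Across all 27022 probe sets, which are not independent replicates, the fold changes of both comparisons correlated with r = 0.774, against 0.5003 in the simulations, and their covariance was 0.217 against 0.126. Where no array was shared, the correlation was 0.330 for GFP-positive replicate 1 with GFP-negative replicate 2 and 0.346 for the reverse. The independent lists hold no shared controls, but the simulations do. Unchanged groups give few calls to share, so the overlap of calls says nothing on the part of shared controls. The correlation and covariance exceeded the simulated ones, and correlations remained where no array was shared. Both argue against the shared controls as the only source of the likeness. Correlations without a shared array use 1 control array for each comparison. The simulations hold no real effects, so how far shared controls add to the overlap of real changes cannot be told.

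The direct comparison of GFP-positive with GFP-negative cells asked whether the sorted fractions of the treated cells differed. Of the 20 gene lists, 3 were called. The germline list was 0.39 higher in GFP-positive cells (0.45 within replicate 1 and 0.55 within replicate 2; camera adjusted p = 4.63e-06, or 0.984 with an estimated correlation), with 26 of 35 members positive and 0 called. Dazl had a signal of 778.8 ± 525.6 in GFP-negative and 2003 ± 215.0 in GFP-positive cells (1.496 ± 0.446), and Gtsf1, Rhox5 and Tex19.1 were at 1.17 ± 0.45, 0.87 ± 0.42 and 0.83 ± 0.41. In the order Dazl, Gtsf1, Rhox5 and Tex19.1 these differences were 0.78, 0.76, 0.34 and 0.34 without GFP-negative replicate 2. Rhox5 and Tex19.1 were at 1.40 and 1.33 without GFP-negative replicate 1 and at 0.45 and 0.45 without GFP-positive replicate 1. The stress and metallothionein list was 0.26 higher (0.28 and 0.20; adjusted p = 8.81e-07, or 0.175 with an estimated correlation), with 23 of 26 members positive and 1, Ddit3, higher when adjusted over the list alone. Ddit3, a transcription factor of the endoplasmic reticulum stress response, was at 1.13 ± 0.20, the heat shock genes Hsp90aa1 and Hspa1a at 0.37 ± 0.21 and 0.56 ± 0.32, and Herpud1 at 0.34 ± 0.21; Hsp90aa1 was at 0.21 without GFP-negative replicate 2. The matrix and fibroblast identity list was lower by -0.155 (-0.13 and -0.10; adjusted p = 0.00599, or 0.984 with an estimated correlation), with 34 of 46 members negative. Prrx1 was at -0.35 ± 0.19, Col1a1, a chain of type I collagen, at -0.52 ± 0.35, Fap at -0.69 ± 0.47 and Timp3 at -0.33 ± 0.25. Col1a1, Fap and Timp3 were at -0.02, 0.0081 and -0.16 without GFP-positive replicate 2, at -1.02, -1.38 and -0.51 without GFP-positive replicate 1 and at -0.32, -0.40 and -0.165 without GFP-negative replicate 1, and Timp3 was at -0.50 without GFP-negative replicate 2.

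No single probe set was called between the sorted fractions, and with the array set as a block the 3 lists called above kept their calls at the fixed correlation (adjusted p = 4.02e-05, 1.83e-07 and 0.000230) and lost them with an estimated one (0.622, 0.467 and 0.916). Limma called 0 of 27022, with 169 at an unadjusted p under 0.05 and a smallest adjusted p of 1.00. Without the trend the count was 0 (289 unadjusted), and with the array set as a block it was 0 (1553 unadjusted), with Ddit3 at the smallest adjusted p of 0.0681. Across all probe sets, which are not independent, the difference between the fractions within replicate 1 correlated with that within replicate 2 at r = 0.056. The germline difference lost its call without GFP-negative replicate 2 (0.19, adjusted p = 0.320) and without GFP-positive replicate 1 (0.18, 0.166), and was 0.84 without either of the other treated arrays. It was 0.87 with the stricter filter, 0.60 with an offset of 7.659 and 0.26 with 4 times the offset. The matrix difference lost its call without GFP-negative replicate 1 (-0.08, 0.780), without GFP-positive replicate 2 (-0.08, 0.536) and after centring each array on its median (adjusted p = 0.0714). With the array set as a block the imprinted list was called as well, at -0.17 (adjusted p = 0.0328, against 0.0738 without the block), but not with an estimated correlation (0.622 with the block).

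The series also asked whether sorting for GFP enriched for cells that the drug had affected. For this, the probe sets changed in the mean of both treated groups against control were taken, a contrast that does not use the difference between the sorted fractions. It called 49 probe sets, 36 higher and 13 lower, over 36 named genes, and 39 of the 49 (79.6%) lay farther from control in GFP-positive than in GFP-negative cells. Of the 36 risen probe sets 27 did so. Among them were those of Dazl, Gtsf1, Rhox5 and Tex19.1 of the germline list and of the keratins Krt8, Krt18 and Krt7. Of the 13 fallen ones 12 did so, among them Ccn3, the growth arrest gene Gas1, the heparin-binding growth factor Ptn, Epha3 and Marcks. These genes were picked after their values were seen. Ereg, Ptgs2, Nes, Nppb, Sprr2k, Sema3e and Phlda1 were the named risen genes that did not, and Lrrc17 was the fallen one. The median difference in the direction of the treatment change was 0.28, and it was 0.21, 0.49, 0.23 and 0.31 in the 4 pairings of a GFP-positive with a GFP-negative array (SD 0.126). With the array set as a block the share was 1288 of 1889 probe sets (68.2%) and the median difference 0.12; no test across probe sets was made, since they are not independent.

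The 49 calls of this contrast became 0 in limma without the trend (1817 at an unadjusted p under 0.05). With it they were 5 without control replicate 1, 11 without GFP-positive replicate 2, 15 without control replicate 2, 27 without GFP-negative replicate 2 and 28 without GFP-negative replicate 1. The median difference was 0.46, 0.42, 0.50, 0.69 and 0.44 without control replicate 1, control replicate 2, GFP-negative replicate 1, GFP-positive replicate 1 and GFP-positive replicate 2. It was 0.62 after median centring.

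**Figure D3:**
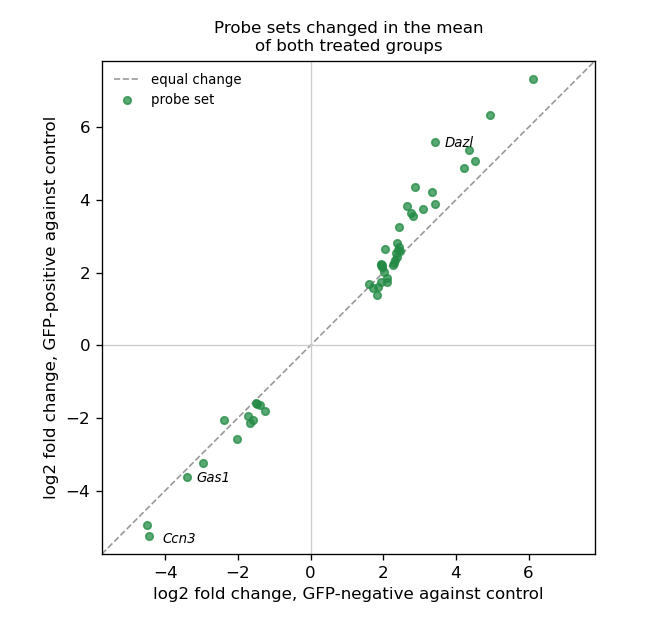
Log2 fold change against control in GFP-negative cells (horizontal) and GFP-positive cells (vertical) for the 49 probe sets changed in the mean of both treated groups; the dashed line marks equal change. For 39 of the 49 probe sets the point lies farther from 0 on the vertical than on the horizontal axis.

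Genes of the X chromosome, which carries the transgene, were not called as a set in any comparison. The median of the 443 measured X-linked genes relative to other genes was -0.03 in GFP-positive against control (adjusted p = 0.709), -0.03 in GFP-negative against control (0.948) and 0.0012 in GFP-positive against GFP-negative cells (0.929). Rhox5 was the X-linked gene called in GFP-positive cells, 1 of 443 against 14 of 12714 autosomal genes called higher (two-sided Fisher's exact p = 0.402). With the array set as a block, 21 X-linked genes (4.74%) and 602 autosomal genes (4.73%) were higher in GFP-positive cells (exact p = 1.00). The list of genes that escape X inactivation was not called in any comparison (adjusted p = 0.709, 1.00 and 0.764 in the order given).

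Xist, the RNA that coats the inactive X, had signals of 5386, 4217 and 3497 on the replicate 1 arrays of control, GFP-negative and GFP-positive cells and of 832.1, 547.4 and 517.5 on the replicate 2 arrays. Its differences were -0.64 ± 1.22 in GFP-positive and -0.46 ± 1.22 in GFP-negative against control and -0.17 ± 1.22 between the sorted fractions, with an SE that holds the difference between the array sets. Within replicate 1 and replicate 2 they were -0.62 and -0.65, -0.35 and -0.58, and -0.27 and -0.08. With the array set as a block the difference of Xist between GFP-positive and control cells passed the test, at the same -0.64 (adjusted p = 0.0301). It did not pass for GFP-negative cells (0.138) or between the fractions (0.906). Leaving out 1 array makes the array sets uneven between groups, and in the fit without a block the differences then ranged from -1.98 to 0.71 in GFP-positive and from -1.90 to 0.97 in GFP-negative cells against control and from -1.61 to 1.27 between the fractions. Of the Y-linked genes, Kdm5d had a signal of at most 116, Eif2s3y of at most 72.0 and Uty of at most 79.3. On control replicate 2, which the labels describe as of mixed sex, Kdm5d was at 93.7, Eif2s3y at 6.9 and Uty at 9.0. The signal of Uba1y reached 247, on a probe set that can bind related transcripts. Dnmt1, the maintenance DNA methyltransferase that the drug traps on DNA, was at 0.46 ± 0.35 in GFP-positive and 0.40 ± 0.35 in GFP-negative cells against control and at 0.06 ± 0.35 between them, and Cdkn1a was at 0.05 ± 0.20 between them, all below the threshold. In GFP-positive cells Dnmt1 was at 0.79, 0.13 and 0.26 without control replicate 1, control replicate 2 and GFP-positive replicate 1. In GFP-negative cells it was at 0.73 and 0.07 without control replicates 1 and 2 and at 0.01 and 0.79 without GFP-negative replicates 1 and 2. Between the fractions it was at 0.45 and -0.33 without GFP-negative replicates 1 and 2 and at -0.14 and 0.26 without GFP-positive replicates 1 and 2, and Cdkn1a was at 0.08, 0.02 and 0.03 without GFP-negative replicate 1, GFP-negative replicate 2 and GFP-positive replicate 2.

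**Figure D4:**
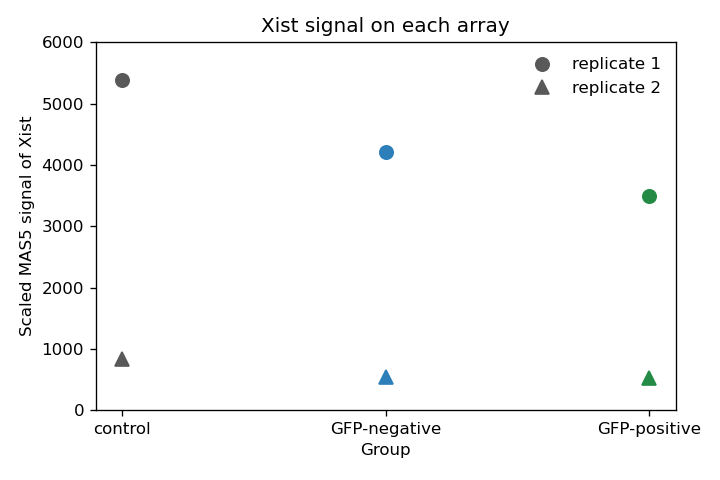
Scaled signal of Xist on each of the 6 arrays by group; circles are replicate 1 and triangles are replicate 2. The replicate 1 arrays lie between 3497 and 5386 and the replicate 2 arrays between 517.5 and 832.1.

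Markers of other cell types and of RNA quality were set beside these groups. The leukocyte marker list stood 0.50 higher in GFP-positive than in control cells (0.44 and 0.49 within the array sets; adjusted p = 0.0329, or 0.665 with an estimated correlation), with 9 of 10 members positive and 0 called. Cd68, Coro1a, Cd14 and Fcer1g reached signals of 186.0 ± 23.9, 152.3 ± 5.8, 243.8 ± 39.7 and 100.1 ± 36.2, from 57.3 ± 37.9, 44.7 ± 36.9, 101.0 ± 110.7 and 29.9 ± 32.3. Their log2 differences were 1.37, 1.37, 1.37 and 1.19, or 0.79, 0.73, 0.80 and 0.55 with 4 times the offset. Without control replicate 2 those of Coro1a, Cd14 and Fcer1g were 0.85, 0.38 and 0.62, without control replicate 1 that of Cd14 was 2.35, and with an offset of 7.659 that of Fcer1g was 1.81. The list moved together with the germline, p53 target and cell cycle lists. Its shift was 0.27 with the mean of the probe sets of a gene. Its call was lost with the block (adjusted p = 0.0628), without a filter on dim probe sets (0.06, adjusted p = 0.229), with a stricter filter (0.202), with the mean of the probe sets of a gene (0.0711), without control replicate 2 (0.49, 0.110), without GFP-positive replicate 1 (0.45, 0.151) and without GFP-positive replicate 2 (0.76, 0.0710). The smooth muscle marker list stood 0.20 higher in GFP-negative than in control cells (0.41 and -0.06; adjusted p = 0.0480, or 0.630 with an estimated correlation and 0.0382 with the block), with 9 of 10 members positive and 0 called, or 1 higher with the block. Des (desmin) was at 2.35 ± 0.44, Actg2 at 0.63 ± 0.27, Smtn at 0.46 ± 0.28 and Cnn1 at 0.32 ± 0.27. Actg2, Smtn and Cnn1 were at 0.27, 0.75 and -0.04 without control replicate 1 and at 0.98, 0.17 and 0.67 without control replicate 2, and Cnn1 was at 0.18 without GFP-negative replicate 2. The call of the list was lost without control replicate 1 (0.03, adjusted p = 0.744), without GFP-negative replicate 1 (0.15, 0.250), without GFP-positive replicate 2 (0.0517), with median centring (0.0566), without a filter (0.0535) and with the mean of the probe sets of a gene (0.0613). The shift was 0.41 without control replicate 2, 0.31 without probe sets that bind related transcripts and 0.32 without GFP-negative replicate 2.

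The lists of skeletal muscle, keratinocyte, melanocyte, endothelial, adipocyte and Schwann cell markers were not called in any comparison, nor were those of the DNA methylation machinery, inflammatory secreted factors and Y-linked genes. Their adjusted p-values in GFP-positive against control cells were 0.0801, 0.415, 0.789, 0.862, 0.415 and 0.709, and 0.797, 0.0801 and 0.897. The ratio of 3' to 5' signal was 0.675 to 0.854 for Gapdh and 1.07 to 1.21 for actin over the 6 arrays. Within replicate 1 the Gapdh ratio was 0.675, 0.700 and 0.698 in control, GFP-negative and GFP-positive cells, and within replicate 2 it was 0.854, 0.835 and 0.792. Control probe sets for added bacterial and phage transcripts and for 18S rRNA, which were not tested, had higher signals in both treated groups than in control within both array sets, and so moved together with the germline, p53 target and cell cycle lists. Those for bioB and cre were also higher in GFP-positive than in GFP-negative cells within both sets, as were the germline and stress lists. For bioB the signals were 654, 748.4 and 1054 within replicate 1 and 830.9, 1188 and 1468 within replicate 2, in the same order of groups. For cre they were 30313, 38345 and 43532, and 42567, 47964 and 56807. For 18S rRNA they were 266.2, 411.5 and 383.1, and 263.2, 367.6 and 288.9.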

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

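The tests for Xist, and those of a probe set fault and of a stress response for Ddit3, were chosen after the results were seen. The criteria of these Ddit3 tests were set again after a first run, as stated with them, and that of male cells was changed and then put back to its first form.

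Ddit3 moved in opposite directions in the sorted fractions. Its signal was 3818 and 4318 in control, 2341 and 2532 in GFP-negative and 5179 and 5536 in GFP-positive cells, a difference between the fractions of 1.13 ± 0.20 (limma adjusted p = 1.00, or 0.0681 with the array set as a block), so the difference did not pass the test. Chance among many probe sets stays open: 193 probe sets had control between both treated groups without overlap, where random order would give 600, although array sets and a shared treatment direction lower that count. A fault of 1 probe set cannot be told apart, since the other, dimmer probe set of Ddit3 differed by -0.219 (SE 0.69). Under the first criterion that value would have counted for a fault. A stronger integrated stress response in GFP-positive cells may also apply. Of 8 further genes taken for stress responses, 3 were higher within both array sets, namely Atf4, Hspa5 and Herpud1. Atf3, Asns, Chac1, Trib3 and Sesn2 were not. The first criterion would have counted this against such a response, and the criterion used leaves it undecided.

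A probe set for the mouse B2 repeat, among the control probe sets used in no comparison, was 1.53 higher on the log2 scale in treated than in control cells. Its signals were 1411 and 757.1 in control, 3744 and 2062 in GFP-negative and 4506 and 2496 in GFP-positive cells. Within the array sets the differences from control were 1.39 and 1.41 in GFP-negative and 1.65 and 1.68 in GFP-positive cells. A brighter probe set for the same repeat differed by 0.24 and 0.05, and by 0.31 and 0.37, and that for the B1 repeat by 0.11 and -0.31, and by 0.20 and -0.31. None of these differences was tested.

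Xist was 6.28-, 7.35- and 6.43-fold lower on replicate 2 than on replicate 1 in control, GFP-negative and GFP-positive cells. A shift of all probe sets of like brightness is argued against, since 2 of 4130 (0.0484%) fell as far as Xist, by -2.74. Male cells among those of replicate 2 cannot be told apart by Y-linked genes. The highest signal of 3 such genes on those arrays was 93.7, for Kdm5d in control, above the 67.7 needed to be kept but near background. No gene was over 0.33 higher in log2 than on replicate 1. On the treated replicate 2 arrays the highest was 28.7, and each of the 3 genes was lower than on replicate 1. These arrays gave no sign of male cells, though signals near background decide little. Loss of the inactive X in some cells stays open as well, as 14 genes that escape X inactivation were higher on replicate 2 by a median of 0.222 (SE 0.165) relative to other genes, with 5 of the 14 lower. Such a loss would lower them, but the value lies within 2 SE of 0. The sort for GFP speaks against both, since per the labels the transgene came from the father, so that sons lack it, and lay on the inactive X. Neither kind of cell should then be GFP-positive, yet Xist was 6.43-fold lower in that fraction. Such cells alone would have to be the larger part of the GFP-positive fraction to lower Xist that far, which argues against both there. The purity of the sort is not given in the sources used here. The label of mixed sex belongs to control replicate 2 and does not cover the treated arrays. In control and GFP-negative cells both stay open. No other biological explanation was tested.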

How the results depend on the processing

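The array sets come from the replicate numbers, and arrays of equal number deviated together (correlations of 0.513, 0.506 and 0.556). With the replicate block the calls were 1679, 966, 0 and 1889 for GFP-positive, GFP-negative, the fractions and the treated mean, against 33, 8, 0 and 49, all of which were among them. With the replicate block and quantile normalization they were 1678, 943, 0 and 1906, with the replicate block and no trend 8, 0, 0 and 8, and with no trend alone 0, 0, 0 and 0 (1674, 1298, 289 and 1817 at an unadjusted p under 0.05, limma). The share of probe sets farther from control in GFP-positive cells was 68.2%, 67.6% and 100% and the median difference 0.12, 0.11 and 0.61 in these 3 blocked fits. Without both rescaled arrays, an alternative chosen after seeing the data like the last 2 blocked ones, the calls were 62, 49, 0 and 124; this leaves 1 array in each treated group, so the spread comes from the 2 controls alone. An adjusted p under 0.10 gave 78, 25, 0 and 140. Calls in GFP-negative cells were 4 with median centring, 3 with an offset of 7.659, 3 with the stricter filter, 3 with only the groups compared and 5 without probe sets that bind related transcripts; median centring gave a share of 89.7% and a median of 0.62. Without a filter the treated mean had 81 calls. With an estimated correlation 0 of 16 lists were called, and with the block as well, chosen after seeing the data, 0 were. The X-linked shift between the fractions turned from 0.0012 to -0.0017 with 4 times the offset, -0.0039 without a filter, -0.029 with the stricter one and -0.0036 without probe sets that bind related transcripts.

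Leaving out 1 array, where a lone array was assumed to vary like the other groups, gave 0 to 35 calls for GFP-positive, 0 to 6 for GFP-negative, 0 for the fractions and 5 to 34 for the treated mean, shares of 80% to 100%, medians of 0.34 to 0.69 and 14 to 20 lists. X-linked shifts ran from -0.042 to -0.015 and from -0.031 to -0.002 against control and from -0.028 to 0.038 between the fractions. A left-out array makes the array sets uneven between groups, so all these values also hold the difference between the sets. Signs turned for Cnn1 (-0.038 to 0.67) and the germline list (-0.14 to 0.72) in GFP-negative cells and the imprinted list (-0.56 to 0.019) in GFP-positive cells. They also turned for Dnmt1 (-0.33 to 0.45) and Fap (-1.38 to 0.0081) between the fractions, and for Xist (-1.98 to 0.71, -1.90 to 0.97 and -1.61 to 1.27). Within the array sets the germline list stood at 0.48 and 0.04 and the imprinted list at -0.28 and -0.22 in these groups. Of 2176 further values under alternatives, 1828 kept direction and side of the threshold, 264 lost it, 72 gained it and 12 turned. No alternative other than leaving out an array turned a named gene. The cause was not tested. Signals near background limit dim genes, whose changes the offset shrinks.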

Other observations

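The 5 gene families below were picked after the largest changes and 15 families of like-named genes had been looked through, so their p-values, adjusted over these 5 alone, are not independent of the data; all tests in this part except those of selection and of a mixture were chosen after the results were seen. Genes of sterol synthesis stood lower in both treated groups, with a median of -0.88 relative to other genes in GFP-positive and -0.91 in GFP-negative cells (camera adjusted p = 2.00e-10 and 3.63e-13, or 0.119 and 0.0884 with an estimated correlation); 1 and 0 of 18 members were positive, and with the array set as a block 10 and 11 were called lower. Hmgcs1, which makes the precursor of mevalonate, was at -1.34 ± 0.44 and -1.37 ± 0.44 (adjusted p = 0.504 and 0.696, or 0.000619 and 0.000810 with the block), and Fdps, the farnesyl diphosphate synthase, at -1.37 ± 0.46 and -1.38 ± 0.46 (0.521 and 0.725, or 0.00914 and 0.0118 with the block). The shift was -1.08 and -0.66 within the array sets in GFP-positive and -1.25 and -0.64 in GFP-negative cells. It was -0.48 in GFP-positive cells without GFP-positive replicate 1 and -0.60 in GFP-negative cells without GFP-negative replicate 1.

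Dual-specificity phosphatases of MAP kinases stood higher by 0.91 and 0.77 (adjusted p = 5.37e-06 and 1.20e-06, or 0.0947 and 0.0601 with an estimated correlation), at 0.69 and 0.96 and at 0.62 and 0.93 within the array sets, with 9 and 10 of 10 members positive and 6 and 5 called higher with the block. Dusp4 was at 1.80 ± 0.40 and 1.82 ± 0.40 (0.246 and 0.367, or 0.000187 and 0.000270 with the block). AP-1 subunits stood higher by 0.94 and 0.89 (0.00224 and 0.000439, or 0.119 and 0.0884 with an estimated correlation), at 0.68 and 1.53 and at 0.66 and 0.93 within the array sets. Of the 7 members 5 and 6 were positive, and 4 and 2 were called higher with the block. Fosl1 rose by 2.14 ± 0.27 in GFP-positive cells (adjusted p = 0.0456). Their shift was 1.52 and 0.52 in GFP-positive cells without control replicates 1 and 2, and 0.28 and 0.03 in GFP-negative cells without control replicate 2 and GFP-negative replicate 1. Ligands of the EGF receptor stood higher by 0.79 and 0.89 (0.0169 and 0.00382, or 0.132 and 0.0884 with an estimated correlation), with Ereg at 1.86 ± 0.27 and 2.09 ± 0.27 (0.0763 and 0.0913, or 0.000157 and 0.000115 with the block) and 2 of 5 members called higher with the block in each group; in GFP-positive cells the call was lost without control replicate 2 (0.00062, adjusted p = 0.0686) and without GFP-positive replicate 1 (0.18, 0.103), and in GFP-negative cells the shift was 0.10 without control replicate 2. It was 0.58 and 1.00 within the array sets in GFP-positive and 0.21 and 1.57 in GFP-negative cells, 1.49 and 1.74 with the stricter filter and 0.38 and 0.41 with 4 times the offset. Without a filter it was 0.57 in GFP-negative cells. Of the 5 ligands 3 were positive in GFP-positive and 4 in GFP-negative cells. Cornified envelope genes stood higher by 0.39 and 1.23 (0.00130 and 1.50e-08, or 0.0947 and 0.0431 with an estimated correlation), and lower in GFP-positive than in GFP-negative cells by -0.53 (0.000421, or 0.126 with an estimated correlation). Within the array sets these shifts were 0.90 and 0.88, 1.25 and 1.17, and -0.49 and -0.35. Of the 13 members 8 and 12 were positive against control. With the block 5 and 6 were called higher against control and 0 between the fractions. With both the block and an estimated correlation 0 families kept a call. The last call was lost without probe sets that bind related transcripts (-0.23, 0.0954) and without GFP-positive replicate 1 (-0.34, 0.0859), and it was -0.31 with 4 times the offset. The first shift was 0.66 and 0.61 without control replicates 1 and 2, 1.19 with the stricter filter, 0.155 without probe sets that bind related transcripts and 0.26 with 4 times the offset or without a filter. The second was 1.90 with the stricter filter and 0.48 without a filter, and the third -0.23 without a filter.

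The larger change of treatment-changed probe sets in GFP-positive cells was weighed against 3 explanations. Selection by chance values is argued against: probe sets picked on 1 array set were farther from control in GFP-positive cells in 83.7% and 79.6% on the other. A difference of scale or gain in the distribution of signals is argued against by a share of 83.3% after quantile normalization, where the pairings had an SD of 6.32. The control probe sets bioB and cre were also higher in GFP-positive than in GFP-negative cells, and a difference in hybridisation that acts otherwise was not tested. A mixture of responding and unresponding cells among the GFP-negative ones was not decided. On the linear scale these cells showed 0.783 of the change for risen and 0.948 for fallen probe sets. The difference of -0.165 lay narrowly within 0.182, by which the risen part differed between array sets. The parts were 0.843 and 0.921 within replicate 1 and 0.661 and 0.923 within replicate 2, lower for risen probe sets in both. A single share of unresponding cells would give all genes the same part. Yet GFP-negative cells lay near GFP-positive ones for Ccn3 (542.4 against 395.2, control 12606) and nearer control for Dazl (778.8 against 2003, control 67.7). These genes were picked after their values were seen, so a mixture stays a hypothesis.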
